A study of Mus musculus with 2 samples.

How the data were processed

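Single-cell 3' libraries of LA2 cells, 1 labelled mock and 1 treated with 4-OHT, were deposited as sparse matrices of UMI counts per gene and barcode, with gene and barcode lists. The mock library is called untreated throughout. The deposited counts were made by the authors with Cell Ranger 5.0 on the mm10 build, per the submitters' processing notes, while the software version in the matrix headers reads 3.1.0, per the file headers. The values were whole numbers and were used as raw counts. The dose was taken as 1 uM, as given in the labels' treatment entry, although the treatment protocol in the labels gives the same number in mM. How barcodes were called is not given in the sources used here. Of 31053 gene identifiers, 30934 were found by identifier in the GENCODE M21 annotation of GRCm38, which supplied coordinates.

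Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, which left out 405 untreated and 136 4-OHT barcodes and kept 99.5% of the UMIs of each library. Scrublet, run through scanpy 1.11.5, marked 0 cells in either library and is taken not to have worked, so doublets were kept. UMIs were summed over the kept cells of each library (168986830 untreated, 141561377 4-OHT) and divided by the total to give CPM, so that 3 UMIs correspond to 0.0178 and 0.0212 CPM. Intervals of sums are exact Poisson, those of ratios come from the exact binomial interval and those of shares are exact Clopper-Pearson, all at 95% and for counting error only. As there is 1 library per group, no test was run and no p-value is given. A gene was called higher or lower at a ratio of 1.5.

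Gene lists, cell type markers and the naming rule were fixed before the data were examined. List medians were taken over members with at least 100 UMIs and placed among 10000 random lists matched in 20 expression bins. Equal weight for each cell moved the all-gene median log2 ratio from -0.10 to -0.25, a shift of -0.15, and median-of-ratios scaling moved it by 0.10, so list values under these settings are read against those medians. The genes named in the text were drawn from Trp53, Cdkn1a, Mdm2, Ccng1, Bax, Phlda3, Zmat3, Bbc3 and Pmaip1; up to 4 members of each list with the largest absolute log2 ratio among those with at least 100 UMIs; the 10 highest and 10 lowest ratios among genes with at least 20 CPM in 1 library, without predicted models and mitochondrially encoded genes; and the 5 targets with the highest and 5 with the lowest relative Fano factor. Ptprc, Col1a1, Pecam1, Sftpc, Epcam, Gls2, Kitl and Ckap2 were named after their values were seen.

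For measures per cell, each cell was thinned without replacement to 8000 UMIs, the lower of the 10th percentiles of both libraries rounded down to a multiple of 500. The rule set beforehand named the shallower library without saying by which measure. The 8000 UMIs were chosen before score shares were computed. By the median the untreated library is shallower, which gives 11000 UMIs, and that depth is reported as an alternative. The share of thinned 4-OHT cells that free RNA alone would give a UMI of a gene was taken from Poisson sampling at the gene's CPM times the share of the CPM of Epcam, Cldn7 and Cldn4 found outside cluster 8, a calculation added after seeing the data. The Fano factor was compared with the median of the 200 genes nearest in mean. Co-variation used genes seen in at least 10% of thinned 4-OHT cells and 1000 random sets. Phases were called from list scores minus matched control genes. Clusters used 2000 variable genes, 30 components, 15 neighbours and Leiden (leidenalg 0.10.2) at a resolution of 0.5. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

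The scripts were tested on simulated data. Poisson counts were drawn for the 4-OHT over untreated comparison with 200 changed genes among 11684. There 95.3% of intervals held the true ratio, and 98% of genes made 2-fold higher and 100% of those made 4-fold higher passed a ratio of 1.5. The intervals assume the same sampling, so this checks the calculation and not variation between cells or libraries. Alternatives were other scalings, cell weights, filters, minimums of UMIs, phase weights, thinning depths, score definitions, correlation measures and cluster settings. Settings restricted to cells with Malat1, without the 6% of cells with the most UMIs, at 11000 UMIs, without thinning for phases, or within cluster 3 were chosen after seeing the data.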

Results

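Single-cell RNA sequencing was used to profile LA2 cells, a mouse lung adenocarcinoma line from the KPR model, in which oncogenic K-ras is active and both copies of p53 are silenced by a removable stop cassette. The cells carry a Cre recombinase fused to a modified oestrogen receptor, so that 4-hydroxytamoxifen (4-OHT) lets Cre excise the cassette and restores p53. One library was made from cells labelled mock, called untreated here, and 1 from cells kept in 1 uM 4-OHT for 16 h. The untreated library held 9263 barcodes with 169874517 UMIs, and the 4-OHT library held 6337 barcodes with 142212569 UMIs. After the cell filter 8858 untreated cells remained, with a median of 17038.5 UMIs and 3801.5 genes, and 6201 4-OHT cells remained, with a median of 20120 UMIs and 3805 genes. With 1 library per group no difference has a replicate check and none was tested, so all intervals are 95% intervals for counting error only and all values describe these libraries. No library of 4-OHT-treated cells without restorable p53 was analysed here, so effects of 4-OHT or Cre themselves are part of every difference.

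The first question was whether Trp53, the gene that Cre is meant to restore, was present as the labels say. Trp53 (ENSMUSG00000059552, GRCm38 chromosome 11, 69580359 to 69591873, plus strand, protein coding) stood at 1.32 CPM in untreated cells (223 UMIs) and 55.3 CPM in 4-OHT cells (7822 UMIs). The ratio was 41.9 (interval 36.6 to 48.0), a log2 ratio of 5.39. In cells thinned to 8000 UMIs, Trp53 was seen in 31.3% of 4-OHT cells (30.1 to 32.5%) and in 1.12% of untreated cells (0.908 to 1.37%). Free RNA in the 4-OHT library would by itself give Trp53 UMIs in 8.54 to 11.4% of its thinned cells, if each cell held the average share estimated from markers of a small cluster as described for the single targets. Without thinning these shares were 55.0% and 2.44%. A 3' tag also reads transcripts that give no protein.

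The known transcriptional targets of p53 were then compared between the libraries. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was 18.9 times higher in 4-OHT cells (interval 18.1 to 19.7), at 261 against 13.8 CPM. Ccng1 was 16.1 times higher (15.5 to 16.7) and Mdm2, the ubiquitin ligase that limits p53, was 12.8 times higher (12.4 to 13.3). Phlda3 was 7.96 times higher (7.69 to 8.25) and Zmat3 was 5.05 times higher (4.80 to 5.31). The proapoptotic gene Bbc3 was 2.67 times higher (2.44 to 2.93) and Bax 2.17 times higher (2.14 to 2.19). Pmaip1, another proapoptotic gene, had 71 UMIs in each library and a ratio of 1.19 (0.847 to 1.68), so a difference was not detectable at this depth.

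**Figure D1:**
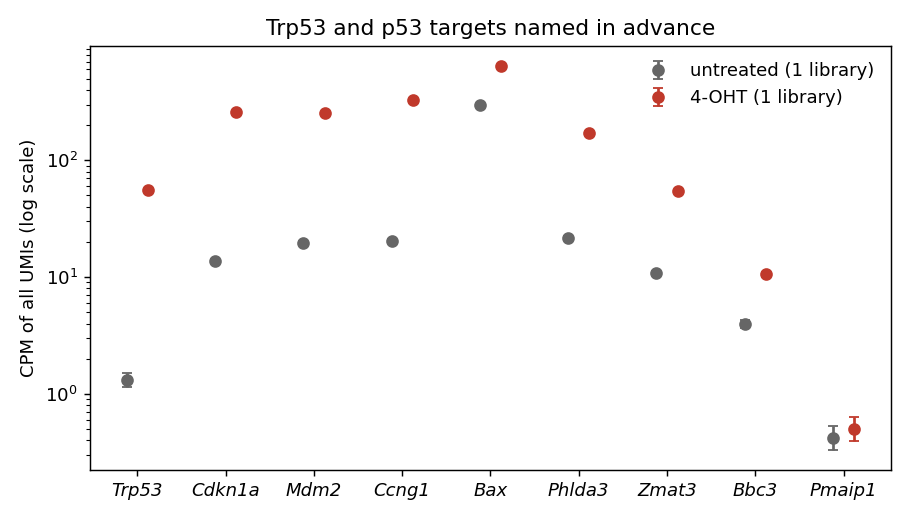
CPM of all UMIs (log axis) of Trp53 and 8 p53 targets in the untreated (grey) and 4-OHT (red) library, 1 library each; bars are exact Poisson 95% intervals, often smaller than the points. All but Pmaip1 were higher in the 4-OHT library, from a ratio of 2.17 for Bax to 41.9 for Trp53.

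Cdkn1a (ENSMUSG00000023067) lies on GRCm38 chromosome 17 from 29090976 to 29100727 on the plus strand. Mdm2 (ENSMUSG00000020184) lies on chromosome 10 from 117688875 to 117710758, and Ccng1 (ENSMUSG00000020326) on chromosome 11 from 40748552 to 40755311, both on the minus strand. Bax (ENSMUSG00000003873, chromosome 7, 45461697 to 45466898, minus strand) overlaps the predicted gene Gm45808 on the same strand, so its count is uncertain to that extent.

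Of the 104 coding p53 targets listed before the data were examined, 92 had at least 100 UMIs. The ratio was at least 1.5 upward for 55 of them and at least 1.5 downward for 5 (Ddb2, Polh, Gls2, Prkab1 and Kitl), with 32 between. Their median log2 ratio was 0.95, or 1.05 above the all-gene median of -0.10, and lay at percentile 100 of 10000 random lists matched on expression. With median-of-ratios scaling 2 targets were lower, and with equal weight for each cell 14. The arrest and feedback targets were higher in 12 of 16 members and lower in 0, including Btg2, an antiproliferative gene, at a ratio of 9.79 (9.14 to 10.5). Of 17 apoptosis targets 10 were higher and 0 lower, led by Trp53inp1 with 39 against 3098 UMIs, a ratio of 94.8 (69.2 to 134), and by the death receptor gene Fas with 13 against 423 UMIs, a ratio of 38.8 (22.5 to 73.6). Among 18 metabolism and antioxidant targets 10 were higher and 2 lower, the latter being the glutaminase gene Gls2 at a ratio of 0.556 (0.507 to 0.611) and Prkab1 at 0.663 (0.630 to 0.697). There the adenylate kinase gene Ak1 had a ratio of 74.0 (54.2 to 104), Dcxr of 15.3 (14.1 to 16.6) and Sesn2, which has a same-strand overlap with Gm12981, of 10.2, a log2 ratio of 3.35 (3.17 to 3.54). The other coding targets were higher in 21 of 31 and lower in 1, Kitl at 0.617 (0.598 to 0.637), with Gdf15, which encodes a secreted stress cytokine, at 53.4 (39.8 to 73.5). Cd80 had 0 untreated and 135 4-OHT UMIs and was at least 53.7-fold higher against a floor of 3 UMIs in the untreated library.

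The DNA repair targets did not share this direction. Of 10 members 2 were higher, Ercc5 with a ratio of 3.89 (3.64 to 4.16) and Polk with 3.66 (3.41 to 3.93). Ddb2 was lower, at a ratio of 0.627 (0.544 to 0.721), as was Polh at 0.647 (0.562 to 0.743). The list median was -0.47 on the log2 scale, or -0.37 relative to all genes. With median-of-ratios scaling 0 members were lower by a ratio of 1.5, and with equal weight for each cell 6. With phases weighted equally 0 were lower and the median was -0.03, as for all genes.

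**Figure D2:**
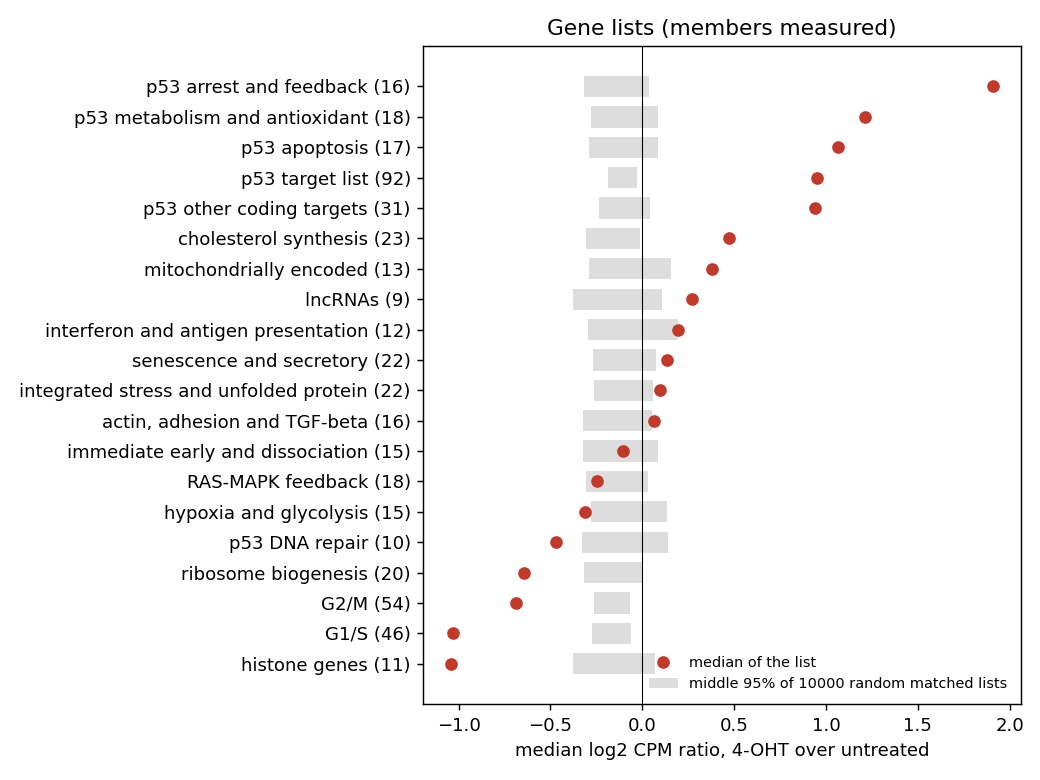
Median log2 CPM ratio (4-OHT over untreated) of each gene list (red points), with the number of measured members in brackets and the middle 95% of 10000 random lists matched on expression (grey bars). The p53 target list lies at 0.95 and the G1/S list at -1.03, both outside their bars.

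Cell cycle transcripts were lower in the 4-OHT library. Of 46 G1/S genes 44 were lower and 0 higher, with a median log2 ratio of -1.03, or -0.93 relative to all genes. Cdc6, which loads the replicative helicase, had a ratio of 0.280 (0.264 to 0.297), and Ung, Clspn and Ccne2 had ratios of 0.288, 0.335 and 0.347. Of 54 G2/M genes 39 were lower and 2 higher, with a median of -0.69, or -0.59 relative to all genes. Ccna2, encoding cyclin A2, had a ratio of 0.479 (0.469 to 0.489) and Aurkb of 0.515 (0.497 to 0.535), while Gtse1 was 4.07 times higher (3.86 to 4.30) and Ckap2 1.69 times higher (1.65 to 1.74). Of 11 histone genes 8 were lower, with Hist1h1b at a ratio of 0.390 (0.384 to 0.396). With the 3 called phases weighted equally in both libraries, 4 G1/S, 1 G2/M and 0 histone genes were lower by that size. This weighting uses the G1/S and G2/M lists themselves to call phases.

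Among all 5021 named genes with at least 20 CPM in 1 library, the highest ratios also included Slc4a11, at 16.0 (14.0 to 18.3), and Ddit4, at 6.50 (6.10 to 6.93). The 10 lowest were led by Cdc6 and Fbxo5, which encodes an inhibitor of the anaphase-promoting complex and had a ratio of 0.324 (0.311 to 0.338). They also held Exo1, Rad51ap1, Dtl, Pclaf, Mcm10 and Mybl2, with ratios between 0.354 for Exo1 and 0.377 for Mybl2.

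Genes of cholesterol synthesis were higher in 9 of 23 and lower in 0, with a median log2 ratio of 0.47, or 0.57 above all genes, and 5 were higher with equal weight for each cell. Fdps, a farnesyl diphosphate synthase gene with a same-strand overlap with Gm43738, had a ratio of 2.16 (2.13 to 2.20) and Insig1 of 1.83 (1.75 to 1.91). Ribosome biogenesis genes were lower in 13 of 20 and higher in 0, with a median of -0.64 and Nolc1 at a ratio of 0.483 (0.478 to 0.489), but 0 were lower with phases weighted equally. Mitochondrially encoded transcripts had a median of 0.38, and among cells with at least 10 Malat1 UMIs per 10000 it was 0.22. Of 9 lncRNAs 3 were higher and 1 lower, with Neat1 at a ratio of 2.29 (2.27 to 2.32) and Malat1 at 1.68 (1.68 to 1.69). The median of this list was 0.27, and -0.06 with equal weight for each cell, where that of all genes was -0.25. Among RAS-MAPK feedback genes 2 were higher and 4 lower of 18, with Egr1 at 0.320 (0.293 to 0.349), Spry1 at 0.614 (0.554 to 0.680) and Ereg at 1.83 (1.75 to 1.92), and 2 were lower with median-of-ratios scaling. Senescence and secretory genes were higher in 5 and lower in 1 of 22, with Ccl2 at 2.27 (2.03 to 2.53), Ccl20 at 1.79 (1.56 to 2.07) and the lamin gene Lmnb1 at 0.540 (0.527 to 0.554). With median-of-ratios scaling 8 of these were higher, and with phases weighted equally 2. Hypoxia and glycolysis genes were neither higher nor lower by that size in any of 15 members, but 3 were lower with equal weight for each cell. Integrated stress and unfolded protein genes were higher in 4 of 22, led by Sesn3 at 2.07 (1.89 to 2.26), and in 1 with equal weight for each cell. Immediate early genes were lower in 2 of 15, Fos at 0.565 (0.543 to 0.588) and Fosb at 0.665 (0.645 to 0.686), the latter being close to the called size. With median-of-ratios scaling 2 of these were higher and 1 lower. Interferon and antigen presentation genes were higher in 3 and lower in 1 of 12, with Bst2 at 1.87 (1.77 to 1.97) and Cxcl10 at 0.419 (0.285 to 0.605). Actin, adhesion and TGF-beta genes were higher in 1 and lower in 1 of 16, Cyr61 at 1.67 (1.60 to 1.75) and Acta2 at 0.568 (0.380 to 0.838), while with equal weight for each cell 0 were higher and 2 lower.

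The title of the series concerns differences between cells, so the target response was measured per cell after thinning each to 8000 UMIs, which left out 290 untreated and 590 4-OHT cells. The summed target UMIs had a median of 38 in 4-OHT cells and 21 in untreated cells. A share of 74.6% of 4-OHT cells (4188 of 5611, exact binomial interval 73.5 to 75.8%) exceeded 31 UMIs, the untreated 95th percentile, against 4.25% of untreated cells. The score is a continuous range and 935 of the 4-OHT cells lay within 2 UMIs of that value. The share rests on the depth, being 59.3% at 4000 UMIs and 81.7% at 11000 UMIs, where 1232 4-OHT cells were left out. Unthinned, the median was 92 against 47 UMIs, and 49.1% of 4-OHT cells exceeded the untreated 95th percentile by UMIs and 85.5% by UMIs per 10000.

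**Figure D3:**
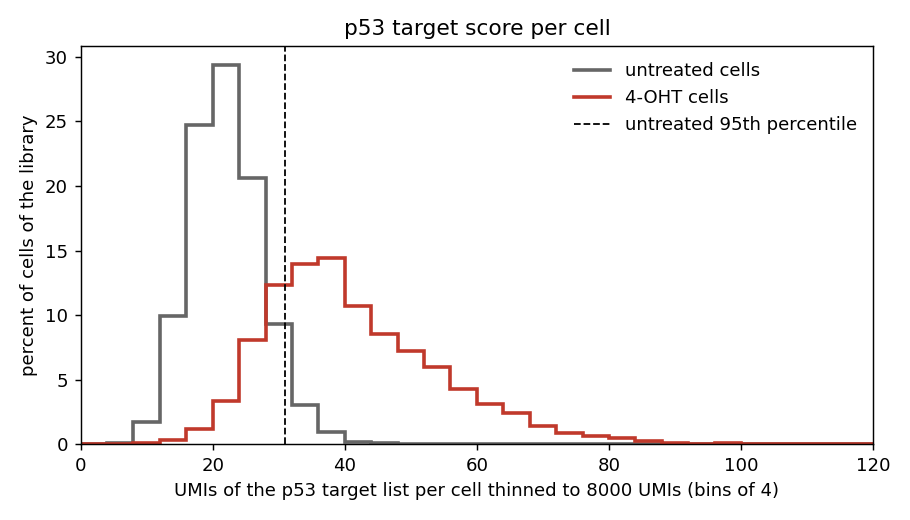
Percent of cells of each library (vertical axis) by UMIs of the p53 target list per cell thinned to 8000 UMIs (horizontal axis, bins of 4) in untreated (grey) and 4-OHT (red) cells. The dashed line is the untreated 95th percentile, 31 UMIs, which 74.6% of 4-OHT cells exceeded.

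Single targets differed in how evenly they were seen. At 8000 UMIs Bax was seen in 98.6% of 4-OHT cells (98.2 to 98.9%), Ccng1 in 82.8%, Cdkn1a in 77.7% (76.6 to 78.8%), Phlda3 in 72.9% and Mdm2 in 70.7% (69.5 to 71.9%). The untreated shares were 89.8%, 14.9%, 10.3%, 15.4% and 14.9%. Unthinned, the shares in 4-OHT and untreated cells were 99.8% and 97.4% for Bax, 91.2% and 31.1% for Ccng1, 89.5% and 19.9% for Cdkn1a, 90.4% and 30.9% for Phlda3, and 84.5% and 30.1% for Mdm2. None of Cdkn1a, Mdm2 and Ccng1 was seen in 3.62% of 4-OHT cells (3.14 to 4.14%) and in 65.0% of untreated cells (64.0 to 66.0%). The Fano factor of Mdm2 in 4-OHT cells was 2.01 times that of genes of like mean, against 1.01 times in untreated cells, and for Ccng1 it was 1.59 against 1.02. Clustering, described last, put most 4-OHT cells in cluster 1, with a median of 2389 genes and 9.24 Malat1 UMIs per 10000, or in cluster 3, with 4875 genes and 56.9 Malat1 UMIs per 10000. Mdm2 stood at 120 CPM in the former and 351 in the latter, and Ccng1 at 185 and 451 CPM. Both genes are among the leading genes of cluster 3, which was made from the same data, so this is no separate result. The relative Fano factors of Nupr1, Areg and Hmox1 were 3.21, 1.82 and 1.69 in 4-OHT cells and 4.43, 1.49 and 1.40 in untreated cells. Gpx1, Prkab1, Siva1, Triap1 and Bax had the lowest relative Fano factors of the 57 targets seen in at least 10% of cells, between 0.942 and 0.958. Of these, Prkab1 and Triap1 had low mean counts, 0.124 and 0.235. As free RNA can give a cell UMIs it did not make, Epcam, which marks a small cluster, was seen in 3.96% of the other 4-OHT cells and 1.70% of the other untreated cells, at median depths of 19989 and 16987 UMIs. Its CPM in these other cells was 20.6% of that of the whole 4-OHT library and 8.56% of that of the untreated library, and over Epcam, Cldn7 and Cldn4 the 4-OHT value was 20.2 to 27.4%. If all of this were free RNA spread evenly, it would give UMIs of Cdkn1a in 34.4 to 43.6% of thinned 4-OHT cells, of Ccng1 in 41.2 to 51.4%, of Mdm2 in 33.5 to 42.6%, of Phlda3 in 24.4 to 31.6% and of Bax in 64.9 to 75.9%.

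Targets were weakly high together in the same 4-OHT cells. Over 1596 pairs of the 57 targets the median Spearman correlation across cells was 0.0245, with 0.0170 as the upper end of the middle 95% of 1000 random sets and 0.0222 as the highest of them. Mdm2 with Ccng1 had the highest value, 0.374, followed by Mdm2 with Cdkn1a at 0.298. At 4000 UMIs the median was 0.0128, with the highest random set at 0.0179, and it also lay below the highest random set at 11000 UMIs, within G1, for genes seen in at least 25% of cells and without the 6% of cells with the most UMIs. Cells with 0 Trp53 UMIs had a mean score of 38.9, those with 1 had 43.8 and those with 2 or more had 49.8. Their median UMIs before thinning also differed, at 20719.5, 24081 and 27090.5. Cells are not replicates, so these values are descriptions of the libraries.

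By the G1/S and G2/M lists, 72.2% of thinned 4-OHT cells (71.0 to 73.4%) were called G1, 8.91% S and 18.9% G2/M, against 9.09%, 49.5% and 41.4% of untreated cells. Unthinned, 73.3% of 4-OHT and 6.90% of untreated cells were called G1. Scored within each library, G1 made up 41.3% of 4-OHT and 26.1% of untreated cells. The lists hold genes that were lower in the 4-OHT library, and the share of free RNA may differ between the libraries, so no cycling is read from these calls. The p53 target list had a median log2 ratio of 0.82 in cells called G1, where 50 of 89 measured members were higher and 7 lower, 0.69 in S, with 45 of 86 higher and 2 lower, and 1.12 in G2/M, with 53 of 89 higher and 2 lower. In S it was 0.40, a ratio of 1.32 and so under the called size, for members with at least 1000 UMIs, of which 17 of 44 were higher and 0 lower. Cdkn1a was 16.1 times higher in G1, 11.1 times in S and 40.7 times in G2/M. Its mean thinned counts in these phases were 1.81, 1.62 and 2.47 in 4-OHT cells and 0.136, 0.158 and 0.0660 in untreated cells. The G2/M ratio thus rests in part on a low untreated level.

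Clustering gave 8 clusters. Cluster 8 had the epithelial markers Epcam, Cldn7 and Cldn4 among its leading genes, but Krt8 and Krt18 of the same list were lower in it than in every other cluster. In untreated cells these keratin genes stood at 3107 and 3662 CPM in cluster 8 and at 4449 and 4020 CPM in cluster 2. Epcam, Cldn7 and Cldn4 stood at 489, 420 and 108 CPM in cluster 8, against 1.56, 1.04 and 0.520 CPM in all other cells. Krt8 and Krt18 were thus found in all clusters, while Epcam, Cldn7 and Cldn4 were largely confined to cluster 8. It held 209 of the untreated cells (2.36%, interval 2.05 to 2.70%) and 69 of the 4-OHT cells (1.11%, interval 0.867 to 1.41%). The difference between these shares is not read as a change. Clusters 1 and 3 came mainly from the 4-OHT library and may be that library, not cell types. Some markers of other lung and stromal cells had few UMIs, with Ptprc, a pan-leukocyte gene, at 5 and 4 UMIs, Col1a1 at 10 and 7, Pecam1 at 19 and 17, and Sftpc at 0 and 0 UMIs in the untreated and 4-OHT library, while other members of these lists were well above this. Of the epithelial markers 2 of 11 were higher and 1 lower, with Krt19 at a ratio of 1.64 (1.63 to 1.65), Cldn4 at 1.84 (1.60 to 2.12) and Grhl2 at 0.639 (0.484 to 0.840), but with phases weighted equally 0 were higher and 3 lower. Mesenchymal markers (9 measured) and gastric and gut markers (6 measured) had 0 members past a ratio of 1.5, while with equal weight for each cell 4 and 1 were lower. Of 7 alveolar type 1 markers Cldn18 was lower, at 0.636 (0.520 to 0.777), but 0 were lower with median-of-ratios scaling. Of 2 airway markers Sox2 was lower, at 0.579 (0.421 to 0.787), and without a minimum of UMIs 5 of 8 were higher and 1 lower. The alveolar type 2, fibroblast, immune and endothelial lists had 1 measured member each, Abca3, Fbln1, Cd68 and Egfl7, with ratios of 1.05, 0.742, 1.36 and 0.849, and the erythroid list had 0. Cells with fewer than 10 Malat1 UMIs per 10000 made up 25.2% of untreated and 27.5% of 4-OHT cells. They were unlike in the 2 libraries, so low Malat1 is not read as poor RNA quality by itself. In the untreated library they had medians of 17034.5 UMIs, 3574.5 genes and 2.66% mitochondrial UMIs, against 17040, 3858 and 3.77% in the other cells. In the 4-OHT library they had 12107 UMIs, 2325 genes and 5.71%, against 25718.5, 4535.5 and 4.48%.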

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

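The barcodes left out by the cell filter, which enter only the alternative with all deposited barcodes, also held p53 target UMIs above the level of those left out of the untreated library. In the 136 barcodes left out of the 4-OHT library Trp53 stood at 27.6 CPM (interval 16.4 to 43.7), Cdkn1a at 192 CPM (160 to 229), Mdm2 at 335 CPM (292 to 382) and Ccng1 at 172 CPM (142 to 207). In the 405 barcodes left out of the untreated library these genes stood at 4.51 CPM (1.23 to 11.5), 6.76 CPM (2.48 to 14.7), 19.2 CPM (11.2 to 30.7) and 5.63 CPM (1.83 to 13.1).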

How the results depend on the processing

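No direction called at a ratio of 1.5 for a list median was turned by any alternative, but medians nearer 0 changed sign in some, as with each cell weighted equally for lncRNAs (-0.06), integrated stress (-0.06) and actin, adhesion and TGF-beta genes (-0.20). The airway markers went from -0.34 over 2 members to 1.14 over 8 without a minimum of UMIs, which is past that ratio in the other direction. Removal of called doublets could not be run for any result, since Scrublet marked 0 cells. No paired analysis was possible because each group has 1 library. Settings limited to cells with Malat1, without the 6% of cells with the most UMIs, at 11000 UMIs, unthinned, or within cluster 3 were chosen after seeing the data. The cause of a move was not tested except where stated. Median-of-ratios scaling gave G1/S -0.93 and G2/M -0.59, and totals without mitochondrial and ribosomal protein genes gave G1/S -0.95 and G2/M -0.60. With each cell weighted equally, which moves the all-gene median by -0.15 and single lists by more or less than that, the log2 values were Trp53 5.12, DNA repair -0.71, G1/S -1.28, G2/M -0.96, histone -1.42, RAS-MAPK -0.41, cholesterol 0.32, ribosome biogenesis -0.88 and glycolysis -0.38. With equal phase weights they were Trp53 5.04, G1/S -0.36, G2/M -0.22, ribosome biogenesis -0.32 and histone -0.20, and 5 in place of 8 lists, the whole p53 target list aside, had a median past a ratio of 1.5. The 4 lists just named no longer passed it, while cholesterol, at 0.59, just did. Without the cells with the most UMIs G2/M was -0.78, and with the Malat1 minimum the mitochondrially encoded list was 0.22. Lower p53 targets numbered 5, and 2 with median-of-ratios scaling, 14 with cells weighted equally and 2 with equal phase weights. In S phase the p53 list was 0.40 at a minimum of 1000 UMIs. The share above the untreated range was 59.3% at 4000 UMIs, 56.7% at the 99th percentile, 67.7% without Bax, 70.8% by ranks, 81.7% at 11000 UMIs and 79.7% with the Malat1 minimum. The median correlation was 0.0128 at 4000 UMIs, 0.0182 within G1, 0.0273 at 11000 UMIs, 0.0294 for genes in at least 25% of cells, 0.0213 with the Malat1 minimum and 0.0101 within cluster 3, and 0.0232 without the cells with the most UMIs. The highest random sets were 0.0179, 0.0267, 0.0303, 0.0344, 0.0170, 0.00446 and 0.0277 in the same order, so it lay above the highest set in the cells with the Malat1 minimum and within cluster 3 but not in the other 5 of these settings. The detection rule was applied anew in each, so the medians covered 35, 53, 66, 31, 60, 65 and 54 targets in the same order. They are not medians over the same pairs. Called G1, S and G2/M in untreated cells were 13.3%, 46.6% and 40.1% at 4000 UMIs, 26.1%, 35.6% and 38.4% scored within the library, 8.01%, 52.0% and 39.97% at 11000 UMIs, and 7.51%, 46.7% and 45.8% with the Malat1 minimum. Unthinned, G1 was 6.90% and S 51.9%, and without the cells with the most UMIs S was 50.6% and G2/M 40.2%. In 4-OHT cells G1 and G2/M were 73.9% and 16.9% at 4000 UMIs and 74.6% and 16.4% without the cells with the most UMIs. G1, S and G2/M were 41.3%, 34.5% and 24.2% scored within the library and 64.9%, 10.6% and 24.6% with the Malat1 minimum. At 11000 UMIs G1 was 70.3% and S 9.90%, and unthinned G2/M was 17.6%. Of values that answer a comparison, 234 stayed within their interval or 1.5 times their count, and 62 moved. Of the other values, which are ratios of single genes and counts of list members, 869 stayed and 411 moved. Few UMIs limit the low targets, as 47 of 104 were seen in under 10% of thinned 4-OHT cells. Depth and low expression were not separated as reasons. Without thinning, the share of 4-OHT cells went from 8.36% to 19.9% for Bbc3, but only from 0.446% to 0.774% for Pmaip1.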

Other observations

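Of the tests below, the comparison of genes per cell at equal depth and that of the lncRNA list were set before their results were seen, and the others after. The bound for unrestored cells was also reworded after its value was seen.

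Of the 6 targets Cdkn1a, Mdm2, Ccng1, Phlda3, Bax and Zmat3, a set not fixed before the data were examined, 799 of the thinned 4-OHT cells (14.2%, interval 13.3 to 15.2%) had UMIs of all 6 and 12 (0.214%, interval 0.111 to 0.373%) of none, against 0 and 421 (4.91%) of untreated cells. Nupr1, a stress-response gene, was a member of each of the 5 lowest target pairs, with a correlation across 4-OHT cells of -0.11 with Areg, -0.09 with Ccng1 and -0.08 with Mdm2.

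Within the 4-OHT library, the 2952 cells of cluster 1 held a median of 2389 genes and 12385.5 UMIs, against 4875 genes and 29424 UMIs in the 2508 cells of cluster 3. Shallower sequencing alone does not account for this, since at 8000 UMIs per cell cluster 1 still held 1870 genes against 2462, or 76.0%. Loss of RNA held in the nucleus may contribute, as Malat1 and Neat1 stood at 21.9% and 11.5% of their cluster 3 CPM. The test set beforehand left these genes out. The 7 other lncRNAs had a median of 52.9%. Kcnq1ot1, Lncpint and Tug1 stood at 10.1%, 11.3% and 37.4%, Pvt1 and Mir17hg at 52.9% and 71.2%, and Snhg12 and Epb41l4aos at 119% and 139%. The list was not chosen for RNA held in the nucleus, so its median cannot decide this and the explanation stays open. In the 1427 untreated cells of cluster 6, Malat1 and Neat1 stood at 880 and 102 CPM, against 1626 and 116 CPM in 4-OHT cells of cluster 1. Kcnq1ot1 stood at 11.6 against 7.77 CPM. These untreated cells still held a median of 3893 genes and 20906 UMIs. Low levels of these RNAs thus did not go with few genes in both libraries. Droplets that hold mainly free RNA also stay open, as Epcam, Cldn7 and Cldn4 stood in cluster 1 at 49.0%, 65.0% and 90.9% of the library's CPM, with a median of 65.0%. A smaller RNA content of cells with restored p53 was not tested.

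The target score spread more widely in 4-OHT cells, with a Fano factor of 4.22 against 1.38 in untreated cells, which counting noise does not give, and called phase accounted for 3.90% of its variance. Clusters 1 and 3 of the 4-OHT library, of unlike Malat1 and gene number, held Trp53 at 33.7 and 72.4 CPM. They held Cdkn1a at 176 and 329 CPM and Phlda3 at 197 and 180 CPM. The clusters were made from these same data, and these genes are among the leading genes of cluster 3 or, for Phlda3, cluster 1. A part of RNA quality in the spread was therefore not separated. Cells in which p53 was not restored may make up all of the 25.4% of 4-OHT cells within the untreated range. That would need 26.5% unrestored cells, a value that takes no free RNA into account. The cells with none of Cdkn1a, Mdm2 and Ccng1 allow 5.57% without free RNA. With free RNA at 20.2% they allow 22.5%, which was taken from the interval ends of the shares and not from the shares themselves. The 20.2% is the lowest of the values for Epcam, Cldn7 and Cldn4 outside cluster 8, which reach 27.4%, and a higher one would allow more. Cluster 1 held more of the same markers, so a larger share of free RNA is possible there and the explanation stays open. Clusters 2, 4, 5, 6 and 7 came mainly from the untreated library. Their 4-OHT cells, 17 to 220 per cluster, held Trp53 at 23.4 to 36.8 CPM and Cdkn1a at 137 to 281 CPM. Their untreated cells held 0.732 to 1.65 and 6.99 to 31.1 CPM. These are averages over cells, a part may be free RNA, and scores were not compared by cluster. They leave the share of unrestored cells unknown.

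The co-variation of targets was also seen within called G1 and under the Malat1 minimum, but neither setting excludes a mix of cells. Within called G1 the median correlation was 0.0182, with 0.0144 as the upper end of the middle 95% of random sets and 0.0267 as the highest set. Phases were called from lists that were lower in the 4-OHT library. Among cells with at least 10 Malat1 UMIs per 10000 the median was 0.0213, with 0.0126 and 0.0170. That minimum keeps 4494 of 6201 4-OHT cells, while 2952 are in cluster 1, so cells of clusters 1 and 3 both remain. Within cluster 3 the median correlation was 0.0101, with 0.00288 as the upper end. Part of the value over all cells may lie between clusters, but the difference cannot show this. The 10% rule was applied anew, so the median within cluster 3 covered 65 targets and that over all cells 57.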
